A study of Mus musculus with 4 samples.

How the data were processed

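Droplet-based 3′-end single-cell RNA sequencing (10x Genomics kit version 3.1, per the labels' protocols) was available for 4 libraries of live CD45-negative CD31-negative lymph node stromal cells from female C57BL/6 mice, 2 controls and 2 Notch2 cKO. Nodes were digested with collagenase P and dispase and depleted of CD45-positive cells before the sort, per the labels. The deposited matrices held raw UMI counts per gene and barcode for 32285 genes, made with Cell Ranger 5.0.1 in batch 1 and 7.1.0 in batch 2, per the file headers, whereas the submitters' processing notes name 5.0.1 for all and genome build mm10. Whether intronic reads were counted and how cells were called is not given in the sources used here. The title of control 2 names Ccl19-Cre while its genotype label names floxed Notch2 without Cre, and the genotype label and the design text were followed. Each library pooled several mice, so a library was taken as the replicate (n = 2 per group).

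Barcodes numbered 9891 in control 1, 8491 in Notch2 cKO 1, 18482 in control 2 and 13452 in Notch2 cKO 2, with medians of 2040, 2834, 5787 and 7243 UMIs. Cells with at least 500 genes, 1000 UMIs and at most 10% mitochondrial counts were kept (9053, 7817, 17014 and 12754). Scrublet in scanpy 1.11.5 made 0, 1, 514 and 0 automatic calls, so its automatic threshold did not work, and the cells with the highest scores were removed at 0.8% per 1000 cells (7.25%, 6.26%, 13.6% and 10.2%). Cells were clustered on 2000 variable genes and 30 principal components after scaling per batch, with 20 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). Lineages were named by marker lists where at least 50% of a list's markers led, at 30 CPM or more and 3 times the median cluster or more, and Pdgfra lay under 200 CPM. Other clusters were taken as fibroblast-like. Fibroblast-like cells were clustered again without the genes called between genotypes, and clusters were named where at least 3 markers and 40% of a list reached 30 CPM and 2 times the median cluster. Clusters that missed this rule, held under 20 cells or had more markers of another class among their 10 leading genes stayed unnamed.

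Some choices were made after the data were seen. The planned clustering split fibroblast-like cells by batch, and a Harmony correction over batches (own implementation, 50 clusters, theta 2, 10 iterations) was added after cluster shares per library had been looked at. Clusterings without Harmony, with Harmony over libraries and with Harmony over batches at 2 resolutions had been tried by then. The naming rule was also set after the data were seen, with 1 other rule tried. A first run, whose numerical libraries were not pinned and which could not be rebuilt exactly, removed slightly different doublets. It gave other cluster boundaries, and the marginal and T-zone classes held other clusters. The results given here come from the pinned run, which was repeated with identical output, and were computed after those of the first run had been seen. Other random seeds of Harmony and Leiden were added to measure how far cluster names depend on such steps.

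Counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3 with batch as a term, which left 1 residual degree of freedom. The replicate numbers pair the libraries because the labels state that they mark the batches. As a check, deviations from the group means of the same-batch libraries correlated at 0.825 across genes in all fibroblast-like and 0.806 in T-zone reticular-like cells, and genes are not independent replicates. Log2 fold changes of the batches correlated at 0.394 and 0.596 (Pearson, across 6493 and 6333 genes at 20 CPM or more). Within-batch log2 differences used a prior of 2 counts. The difference between classes was tested with libraries as a block. The 16 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01), shares with exact permutation tests and 95% Clopper-Pearson intervals (scipy 1.17.1). Where a symbol was listed more than once, the copy with most counts was used. Gene positions were looked up by identifier in an annotation of the mm10 build (134 of 134 found).

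The designs with their tests, the gene lists, the marker lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule named Notch2, 9 fixed genes (Ccl19, Ccl21a, Il7, Grem1, Bst1, Cxcl13, Madcam1, Cd34 and Pi16), and per direction the 10 (all fibroblast-like and T-zone reticular-like cells) or 5 (other classes) largest log2 fold changes among genes past the test with 1 sign in both batches and a mean of at least 20 CPM, with predicted, ribosomal, mitochondrial and haemoglobin genes passed over, and up to 4 members per list with the lowest adjusted p. Some of the genes so picked are not reported here. The alternatives fixed then were no batch term, no TMM, DESeq2 1.42.0, no low-count filter, each library left out (fitted without the batch term, the lone library being taken to vary like the others), a looser filter (200 genes, 500 UMIs, 20%), a stricter one (1000 genes, 2000 UMIs, 5%), no doublet removal, clustering on all variable genes, at resolutions 0.5 and 2 or of each batch alone, an edgeR test of cell numbers, no library block, an estimated correlation in camera, and fry. Alternatives added after the data were seen were no Harmony, Harmony over libraries, other random seeds, named classes alone, the inflammatory cluster or the T-zone clusters left out, the 2 T-zone clusters that pass the check on all genes, and each library left out for the shares.

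The steps were tested on simulated counts with 50 genes at each of 4 fold changes. Within a batch the other genes had the same mean in both groups, and the dispersion trend came from the same fit. No simulated genotype effect differed between batches, so the results describe such data and are no check of the calls made here. In the fit of all fibroblast-like cells (16990 genes) 8%, 62%, 100% and 100% of genes changed by 1.5, 2, 4 and 8 times were recovered, and 1.46% of 137 calls were unchanged genes. In T-zone reticular-like cells (14902 genes) these shares were 0%, 66%, 100% and 100%, and 6.99% of 143 calls were unchanged genes. The fits without the batch term and without control 1 recovered 0% of the genes at every fold in both. Camera with a preset correlation called the changed list (adjusted p = 8.36e-14 and 3.49e-19) and 0 of the unchanged lists, whereas with an estimated correlation the changed list had adjusted p = 0.980 and 0.938. The simulated genes were drawn independently of one another, so false calls for lists of correlated genes were not tested.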

Results

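Single-cell RNA sequencing (droplet-based, counting unique molecular identifiers, UMIs, from transcript 3′ ends) was performed on live CD45-negative CD31-negative stromal cells sorted from axillary, brachial and inguinal lymph nodes of female mice aged 12 weeks. The question named by the series title was how Notch2, a cell-surface receptor of the Notch pathway, takes part in fibroblast specialization and in the niches of T cells. There were 2 control libraries and 2 libraries from mice in which Cre recombinase under the Ccl19 promoter was combined with floxed Notch2 (Notch2 cKO), with 1 library of each group in each of 2 batches. Batch 1 pooled 6 mice per library and its groups were not littermates, whereas batch 2 pooled 3 littermate mice per library. Control 1 carried Ccl19-Cre without floxed Notch2, and control 2 carried floxed Notch2 without Cre. The labels give a fluorescent reporter to both libraries of batch 1 and to neither of batch 2. Total UMIs were 21533049 in control 1, 25644596 in Notch2 cKO 1, 119002408 in control 2 and 108144616 in Notch2 cKO 2. After filtering and doublet removal 8397, 7328, 14698 and 11453 cells were kept in the same order, of which 98.1%, 97.2%, 82.7% and 84.5% were fibroblast-like. Fibroblast-like cells had median depths of 2086, 2913, 6401 and 7933 UMIs.

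Notch2 (ENSMUSG00000027878, mm10 chromosome 3, 98013527 to 98150361), the targeted gene, was measured first. In all fibroblast-like cells it stood at 40.5 CPM (counts scaled to a common library total) in control 1 and 19.9 in Notch2 cKO 1, and at 58.3 in control 2 and 36.2 in Notch2 cKO 2. The log2 fold change of Notch2 cKO against control was -0.85 (SE 0.19, 2 libraries per group), with an adjusted p of 0.0691 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Notch2 fell in T-zone reticular-like cells (log2 fold change -1.05, adjusted p = 0.00895) and in Cxcl9- or interferon-high reticular-like cells (-1.02, adjusted p = 0.0164) by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Values were -1.11 in marginal reticular-like, -0.51 in follicular dendritic-like, -0.39 in adventitial-like and -0.66 in perivascular-like cells, none past the test, and the adventitial-like value was 0.23 in batch 1 and -0.81 in batch 2. That value pools 2 clusters with unlike levels of Notch2. In cluster 6 it was lower in Notch2 cKO in both batches (32.4 and 14.6 CPM, and 54.6 and 44.3), and in cluster 14 it stood at 95.5 and 112, and 135 and 122. The labels do not say which exons were floxed, so 3′-end counts of Notch2 may include transcripts of the recombined gene and are no check of the deletion. Notch2 passed in no class without the batch term, at -0.98 and -1.02 in T-zone and interferon-high cells.

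Across all fibroblast-like cells Cilp (ENSMUSG00000042254, chromosome 9, 65265180 to 65280605), a cartilage-associated matrix protein, averaged 39.3 ± 9.43 CPM in controls and 555 ± 259 in Notch2 cKO (SD, n = 2), a log2 fold change of 3.75 (SE 0.38). Ncam1, a neural cell adhesion molecule, rose from 15.6 ± 7.96 to 143 ± 14.9 CPM (log2 3.27, SE 0.32). Cxcl14, a chemokine, rose from 6.88 ± 3.93 to 60.1 ± 18.0 CPM (3.23, SE 0.23), and Sfrp1, a secreted Wnt antagonist, from 49.6 ± 6.63 to 232 ± 45.8 CPM (2.22, SE 0.20). Adamtsl2 (log2 5.26), Lingo2 (3.58), Adamts15 (3.32), Ecrg4 (2.93), Fhl2 (2.62) and Htr1f (2.52) completed the 10 largest increases of the naming rule. Control counts were near 0 for Adamtsl2 (0.284 and 1.27 CPM, log2 7.56 and 4.17 in the batches) and in control 1 for Lingo2 (0.625 CPM). The size of these 2 folds is therefore uncertain. Igfbp2 (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474), which binds insulin-like growth factors, fell by 3.34 on the log2 scale (SE 0.37), from 80.6 ± 13.4 to 8.41 ± 4.98 CPM. Ptn, a heparin-binding growth factor, fell by 2.88 (SE 0.41), from 331 ± 47.2 to 50.6 ± 34.4 CPM, and Lif, a cytokine of the interleukin 6 family, by 2.50 (SE 0.49). Frmd5 (-2.79), Ntng1 (-2.65), Notch3 (-2.24), Apoc1 (-2.24), Pi15 (-2.05) and Tspan7 (-1.97) were also among the 10 largest decreases.

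Of 17302 genes tested in all fibroblast-like cells, 202 rose and 139 fell by edgeR's quasi-likelihood test with batch as a term and Benjamini-Hochberg adjustment, and 340 of the 341 had the same sign in both batches. With batch as a term the test favours genes whose batches agree, so this is no independent replication. Of all 6493 genes at 20 CPM or more, 57.1% had the same sign. Adjusted p of the 19 genes named above ran from 0.00107 (Lingo2) to 0.0457 (Lif) in this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Among genes followed in every comparison, Madcam1, an addressin for lymphocytes, fell from 31.7 ± 0.920 to 7.55 ± 0.842 CPM (log2 -2.07, SE 0.20). Ccl19 (ENSMUSG00000071005, chromosome 4, 42754525 to 42756577), a T-zone chemokine, averaged 3809 ± 493 CPM in controls and 1457 ± 505 in Notch2 cKO (log2 -1.43, SE 0.39), which missed the test. Ccl21a (0.12), whose counts cannot be told from those of near-identical gene copies, Il7 (0.06), Grem1 (0.73), Bst1 (0.11) and Cxcl13 (0.27) did not pass either. Cd34 (-0.03) and Pi16 (0.45), markers of adventitial fibroblasts, did not pass and had opposite signs in the batches, at 0.93 and -0.95 for Cd34 and 2.41 and -1.42 for Pi16. By edgeR without the batch term 0 genes were called (244 up and 193 down at an unadjusted p under 0.05). With 3 libraries edgeR called 0 without control 1 (121 up and 109 down), without Notch2 cKO 1 (147 up and 180 down) or without control 2 (219 up and 139 down) and 6 without Notch2 cKO 2. DESeq2 with the batch term called 449 genes, library-size scaling without TMM factors called 67 up and 29 down (69.8% up against 59.2%), and leaving out the T-zone reticular-like clusters left 11 called genes.

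The 16 gene lists fixed beforehand were then compared across all fibroblast-like cells, with counts by edgeR's test. Of 10 measured Notch target genes 4 fell and 0 rose, and adjusted over the list alone 6 fell and 0 rose. Notch3, itself a receptor, fell from 144 ± 14.1 to 30.8 ± 8.96 CPM (log2 -2.24), Hes1, a transcriptional repressor, from 207 ± 6.44 to 64.2 ± 26.5 CPM (-1.75), Heyl by 2.29 and Hey2 by 1.80 on the log2 scale. Of 14 contractile and mural genes 1 fell (Myh11, smooth muscle myosin heavy chain, log2 -1.90), and adjusted over the list alone 3 fell and 0 rose. Perivascular-like cells, which also hold Notch3 and Myh11, made up 0.50% and 0.901% of control 1 and Notch2 cKO 1 and 14.2% and 11.7% of control 2 and Notch2 cKO 2. Of 12 inflammatory cytokine and chemokine genes 3 fell (Lif, the neutrophil chemokines Cxcl2, log2 -1.43, and Cxcl5, -1.22), and adjusted over the list alone 6 fell. Limma's camera test with a preset correlation called the Notch target (adjusted p = 1.65e-05), contractile (adjusted p = 3.03e-05) and inflammatory (adjusted p = 4.51e-04) lists lower, but with an estimated correlation the adjusted p was 0.980 for each of them.

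Some genes of antigen presentation and of the Wnt and bone morphogenetic protein (BMP) pathways rose in all fibroblast-like cells. Of 11 antigen presentation genes 4 rose and 0 fell by edgeR's test, and adjusted over the list alone 5 rose. They were the MHC class II genes H2-Aa (50.3 ± 22 to 173 ± 82.0 CPM, log2 1.77), H2-Eb1 (1.70) and H2-Ab1 (1.13) and the class II chaperone Cd74 (1.72). Beside them, clusters led by T cell markers that held mixed leukocytes made up 0.679% of control 1 and 1.66% of Notch2 cKO 1, and 1.31% of control 2 and 1.87% of Notch2 cKO 2. Ptprc, which encodes the leukocyte antigen CD45, stood at 0.164, 0.360, 0.548 and 0.488 CPM in fibroblast-like cells of control 1, Notch2 cKO 1, control 2 and Notch2 cKO 2. Lyz2, a lysozyme gene of macrophages, was higher in both batches there (1.31 and 2.92 CPM in batch 1, 3.71 and 7.53 in batch 2), as were the complement gene C1qa (0.218 and 0.494, 0.417 and 1.0) and the B cell gene Cd79a (1.36 and 2.47, 2.77 and 3.30). Median log2 fold changes in the batches were 0.92 and 0.46 for 6 macrophage markers and 0.99 and 0.40 for 5 dendritic cell markers. Cd74 stood at 341, 1061, 238 and 882 CPM there and at 146, 111, 20.0 and 37.3 CPM in perivascular-like cells. In batch 2 Cd74 was also higher in Notch2 cKO in Schwann cells (7.51 and 41.5 CPM, 91 and 73 cells). The same held for epithelial cells (12.8 and 89.5 CPM, 52 and 29 cells). RNA carried over from other cells was not tested for it. Of 13 Wnt and BMP ligands and antagonists 2 rose (Sfrp1 and Bmp4, log2 1.10) and 0 fell, and adjusted over the list alone 5 rose. Limma's camera test with a preset correlation called both lists higher, at adjusted p = 4.51e-04 for antigen presentation and adjusted p = 9.49e-04 for the Wnt and BMP list, against an adjusted p of 0.980 with an estimated correlation.

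Of 12 adventitial and progenitor-like fibroblast genes in all fibroblast-like cells 1 rose (Ly6a, log2 1.26), with 2 up adjusted over the list alone. Of 16 interferon response genes 0 passed by edgeR, with 1 down adjusted over the list alone (Isg15, log2 -0.88). Limma's camera test with a preset correlation gave adjusted p = 0.0459 for each, higher for the adventitial and lower for the interferon list, and adjusted p = 0.982 and 0.980 with an estimated correlation. The median of the adventitial list was 1.64 in batch 1 and -0.64 in batch 2. Dll4, a Notch ligand, rose (log2 1.66) and Notch3 fell among 13 Notch receptors, ligands and cofactors, with 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.726). Of 9 B-zone and marginal reticular factors 1 fell (Madcam1), with 2 down adjusted over the list alone (camera adjusted p = 0.965), and the list had a median of 0.01 and a mean of -0.34. Of 9 retinoid pathway genes 1 fell (Cyp26b1, which degrades retinoic acid, log2 -1.45), also adjusted over the list alone (camera adjusted p = 0.906), with a median of 0.12 and a mean of -0.15. Over all genes and adjusted over the list alone, edgeR called 0 of 13 T-zone reticular cell factors (camera adjusted p = 0.542), 0 of 22 extracellular matrix genes (0.815), 0 of 13 lymphotoxin and NF-kB pathway genes (0.965), 0 of 8 complement genes (0.542), 0 of 12 immediate early and dissociation genes (0.965) and 0 of 10 cell cycle genes (0.965). The immediate early list (median 0.06, mean -0.03) and the cell cycle list (median 0.06, test direction down) differed in sign between measures.

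**Figure D1:**
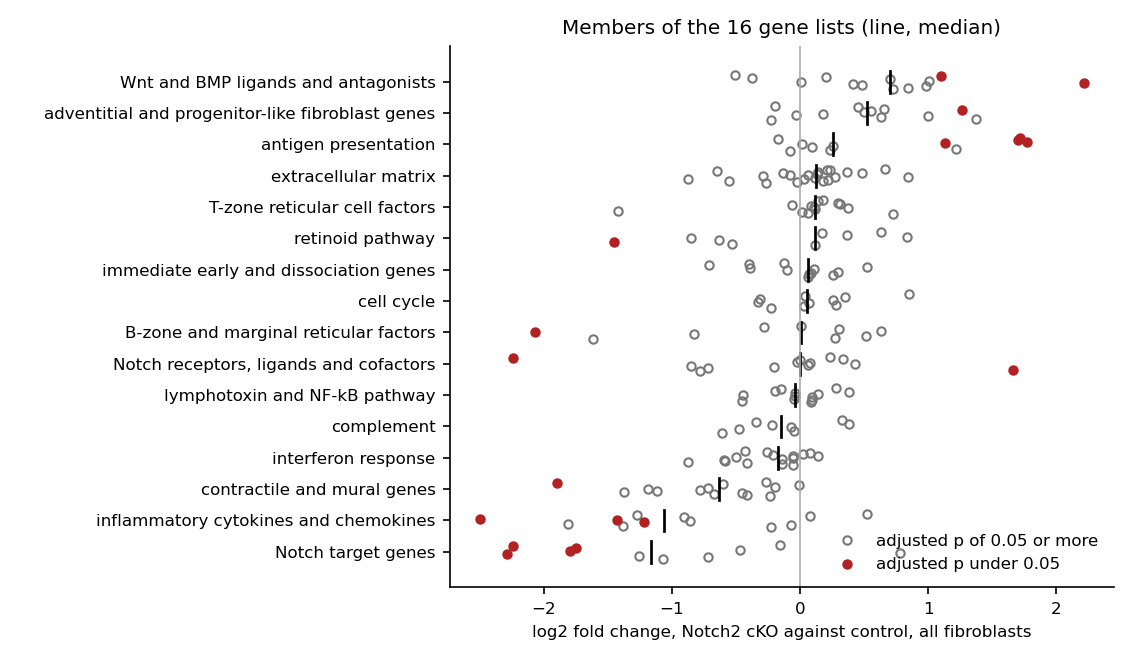
Log2 fold changes (x axis, Notch2 cKO against control in all fibroblast-like cells) of the members of the 16 gene lists, with a line at each list's median. Filled points passed edgeR's test, such as Notch3 at -2.24 and Sfrp1 at 2.22.

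Within T-zone reticular-like cells (clusters 0, 1, 3 and 11), named by T-zone markers such as Ccl21a, 9 of the 10 largest increases were seen in genes that averaged under 6 CPM in controls. Other clusters held the T-zone chemokines too, such as cluster 10 with 8018 and 7594 CPM of Ccl19 and 13620 and 10070 of Ccl21a in control 1 and control 2. Cxcl14 rose from 0.641 ± 0.0753 to 85.8 ± 20.9 CPM (SD, n = 2, log2 6.99, SE 0.29) and A2m, which encodes a protease inhibitor, from 0.670 ± 0.199 to 52.4 ± 20.8 CPM (6.22, SE 0.29). Ncam1 rose from 4.71 ± 2.40 to 154 ± 31.7 CPM (4.97, SE 0.33) and Cilp, the gene above that range, from 36.1 ± 0.876 to 740 ± 342 CPM (4.27, SE 0.34). Adamtsl2 (log2 6.77), Megf6 (4.93), Ccdc3 (4.92), Emp1 (4.83), Smoc2 (4.78) and Lnx1 (4.31) were the others. Igfbp2 fell from 161 ± 4.39 to 11.5 ± 7.70 CPM (log2 -3.92, SE 0.33). Ntrk2, a neurotrophin receptor, fell from 63.4 ± 7.32 to 8.05 ± 0.497 CPM (-2.96, SE 0.22) and Ccl19 from 6452 ± 42.5 to 1908 ± 715 CPM (-1.81, SE 0.41). Ntng1 (-3.37), Frmd5 (-3.08), Meg3 (-3.04), Glycam1 (-2.96), Madcam1 (-2.91), Colec11 (-2.76) and Notch3 (-2.74) also fell. Cxcl13, a B cell chemokine, rose from 305 ± 272 to 598 ± 426 CPM (log2 1.12, SE 0.28; -0.07 without Notch2 cKO 2), whereas Ccl21a (-0.20), Il7 (-0.04), Grem1 (0.58), Bst1 (-0.19), Cd34 (1.35) and Pi16 (0.43) did not pass. The direction of Cxcl13 turned with the stricter cell filter. Within cluster 3 Cxcl13 was lower in Notch2 cKO in both batches (49.4 and 17.5 CPM, and 152 and 98.1), and in clusters 0, 1 and 11 the batches went opposite ways.

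Of 15161 genes tested in T-zone reticular-like cells, 529 rose and 513 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1027 of the 1042 with the same sign in both batches. The test favours such genes here too, and 61.7% of all 6333 genes at 20 CPM or more had the same sign. Cluster 0 held 33.0% and 29.5% of the fibroblast-like cells in Notch2 cKO 1 and 2 against 0.121% and 0.173% in control 1 and 2, whereas clusters 1 and 3 held most of these cells in the controls (14.5% and 23.9% in control 1, 19.9% and 11.3% in control 2). Once the genes called between genotypes were counted, clusters 0 and 3 had more markers of another class than of their own among their 10 leading genes, and clusters 1 and 11 alone gave 140 genes up and 124 down, 205 of them shared with the 1042. In clusters 1 and 11 the log2 fold changes of Glycam1 (1.70), Cxcl9 (0.38), Myl9 (0.43), Cxcl13 (-0.22) and Sfrp2 (-0.41) had the opposite sign. Taken singly, cluster 1 gave 93 up and 91 down, cluster 3 gave 16 and 14 and cluster 11 gave 72 and 63. Without the batch term edgeR called 0 genes (404 up and 361 down at an unadjusted p under 0.05) and DESeq2 with it 605, whereas edgeR called 0 without control 1, Notch2 cKO 1, control 2 or Notch2 cKO 2 (from 211 to 357 up and from 222 to 372 down unadjusted). A stricter cell filter gave 66 genes, and other random seeds of the clustering gave 1042, 678 and 1043, of which 996, 598 and 983 were shared.

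**Figure D2:**
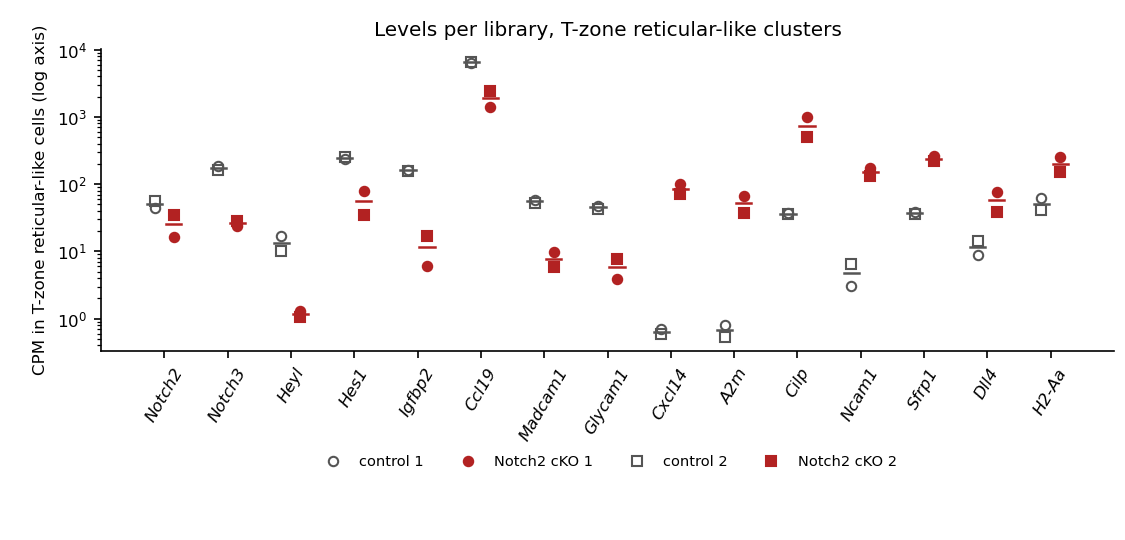
CPM (y axis, log scale) of 15 genes in T-zone reticular-like cells of each library, with lines at group means. Notch3 averaged 175 CPM in controls and 26.1 in Notch2 cKO, and Cxcl14 averaged 0.641 and 85.8.

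In T-zone reticular-like cells 6 of 9 measured Notch target genes fell and 1 rose (Lfng, a glycosyltransferase that modifies Notch, log2 1.73, named after its values were seen) by edgeR, with 7 down and 1 up adjusted over the list alone. Notch3 (ENSMUSG00000038146, chromosome 17, 32120820 to 32166852) fell from 175 ± 20.1 to 26.1 ± 2.96 CPM (log2 -2.74, SE 0.24). Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796) fell from 242 ± 10.6 to 56.4 ± 30.3 CPM (-2.22, SE 0.30), Heyl by 3.4 and Hey2 by 2.21 on the log2 scale. Inside cluster 3, however, Notch3 was not lower (226 and 290 CPM in batch 1, 227 and 260 in batch 2). Heyl stood there at 22.3 and 23.35 CPM in batch 1 and 20.0 and 14.8 in batch 2. Of 12 contractile genes 3 fell (Myh11, log2 -2.18, Tpm2, -1.69, and Myl9, -0.84), with 6 down adjusted over the list alone. Inside cluster 3 Myh11 was higher in Notch2 cKO in both batches (161 and 200.5 CPM, and 197 and 248). In clusters 0, 1 and 11 it was lower in both. Of 15 interferon genes 2 fell (Isg15, -1.39, and Cxcl9, -1.34), with 4 down adjusted over the list alone. Of 12 inflammatory genes 4 fell (Lif, -2.05, Il6, -1.93, Ccl11, -1.85, and Cxcl2, -1.07), also adjusted over the list alone. Of 11 adventitial genes 6 rose, among them Ly6c1 (3.61), Ly6a (2.28), Sema3c (1.94) and Ackr3 (1.86), and Fn1 fell (-1.06, named after its values were seen), with 7 up and 2 down adjusted over the list alone. Of 12 Wnt and BMP genes 5 rose (Sfrp1, 2.70, Sfrp4, 2.26, Bmp2, 1.45, Sfrp2, 1.08, and Bmp4, 0.83), also adjusted over the list alone. Of 11 antigen presentation genes 4 rose (H2-Aa, 1.95, H2-Eb1, 1.72, Cd74, 1.69, and H2-Ab1, 1.10), with 5 up adjusted over the list alone. Directions turned with the stricter cell filter for Ackr3 (-0.87), Sfrp2 (-1.3), Cxcl2 (0.17) and Myl9 (0.56), and with the looser filter for Cxcl9 (0.93). Limma's camera with a preset correlation called these 7 lists, at adjusted p of 1.25e-05 (Notch targets), 3.18e-05 (contractile), 8.84e-04 (interferon), 0.0189 (inflammatory), 0.00133 (adventitial), 2.97e-04 (Wnt and BMP) and 0.00465 (antigen presentation). None held with an estimated correlation, at adjusted p = 0.753 for the Notch target, interferon, adventitial and antigen presentation lists, adjusted p = 0.759 for the contractile list and adjusted p = 0.760 for the inflammatory and the Wnt and BMP lists.

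The remaining 9 lists did not pass camera in T-zone reticular-like cells. Dll4 rose (log2 2.21) and Notch1 (-0.97), Notch2, Notch3 and Jag1 (-0.96) fell among 11 Notch receptors and ligands (Notch1 was 0.0621 with the stricter filter), with 2 up and 4 down adjusted over the list alone (camera adjusted p = 0.321). Among 8 B-zone and marginal factors Sox9 (1.55) and Cxcl13 rose and Madcam1, Tnfsf11 (a cytokine of marginal reticular cells, -1.67, but 0.18 without control 2) and Cr2 (-2.25) fell, also adjusted over the list alone (camera adjusted p = 0.334). Among 22 matrix genes Lum (2.19) and Eln (1.14) rose and Col14a1 (-1.16) and Postn (-1.47) fell, also adjusted over the list alone (camera adjusted p = 0.272). Eln was -0.14 with the stricter cell filter, and Col14a1 was 0.78 with the looser filter and 0.51 with random seed 2. Aldh1a3 (-2.85), which makes retinoic acid, and Cyp26b1 (-1.63), which degrades it, fell among 7 retinoid genes (camera adjusted p = 0.0855) and Ccl19 fell among 13 T-zone factors (0.626), and these were also the calls adjusted over the list alone. The list of 8 complement genes had a camera adjusted p of 0.321. By edgeR 0 of 13 NF-kB pathway (camera adjusted p = 0.465), 0 of 12 immediate early (0.235) and 0 of 10 cell cycle genes (0.321, with a median of 0.06 and the test direction down) passed, over all genes or adjusted over the list alone.

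Cxcl9- or interferon-high reticular-like cells (cluster 10) showed the same direction for several of these genes. Cilp rose from 19.6 ± 2.16 to 581 ± 215 CPM (SD, n = 2; log2 4.75, SE 0.38), and Grem1, a BMP antagonist, from 275 ± 12.1 to 606 ± 117 CPM (1.12, SE 0.33). Adamtsl2, Cxcl14, A2m and Megf6 averaged between 0 and 1.3 CPM in the controls and between 41.7 and 82.8 CPM in Notch2 cKO, and no fold is given because control counts were near 0. Ptn (log2 -5.21), Ntrk2 (-3.96), Glycam1 (-3.66), Lif (-3.63), Madcam1 (-1.94) and Ccl19 (-1.80) fell, whereas Ccl21a (0.17), Il7 (0.24), Bst1 (0.10) and Cxcl13 (0.40) did not pass. Of 10501 genes 304 rose and 369 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without the batch term edgeR called 0 (270 up and 290 down unadjusted), without control 1, Notch2 cKO 1, control 2 or Notch2 cKO 2 also 0 (from 184 to 266 up and from 136 to 398 down unadjusted), and DESeq2 with the batch term called 146. Without TMM factors the median of all genes was 0.13 rather than 0.01 and 59.8% of the calls were up against 45.2%.

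In marginal reticular-like cells (cluster 9) Cilp rose from 20.2 ± 8.01 to 393 ± 408 CPM (SD, n = 2; log2 3.70, SE 0.34), and so did Apln, the ligand of the apelin receptor (3.41), Aqp1, a water channel (2.68), and Ecrg4 (2.38), whereas Car3 averaged 3.33 and 40.9 CPM (log2 3.51). Vtn, which encodes vitronectin, fell from 412 ± 87.1 to 106 ± 28.6 CPM (log2 -1.97, SE 0.28), as did Lepr, the leptin receptor (-1.90), Il6 (-2.03), Il31ra (-2.12) and Pgf (-2.25). Ccl19 (-0.90), Ccl21a (0.03), Il7 (-0.13), Grem1 (0.13), Bst1 (-0.09), Cxcl13 (0.61) and Madcam1 (-1.4) did not pass. Of 10357 genes 62 rose and 70 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. EdgeR called 0 without the batch term (55 up and 50 down unadjusted), 0 without Notch2 cKO 1, control 2 or Notch2 cKO 2 (from 50 to 330 up and from 65 to 112 down unadjusted) and 1 without control 1, and DESeq2 with the batch term called 18. Other random seeds of the clustering put 1524, 3974 and 2963 cells into this class instead of 1352 and gave 29, 37 and 31 genes, of which 28, 32 and 26 were shared with the 132.

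In follicular dendritic-like cells (cluster 13) Aqp1 rose from 23.5 ± 24.2 to 191 ± 135 CPM (SD, n = 2; log2 3.6, SE 0.41), and Ccbe1 (3.66) and Prkcb, a protein kinase (3.30), rose. Smoc2 averaged 0 CPM in controls and 63.1 in Notch2 cKO, and Adamts15 0 and 43.0 CPM, with no fold given for either because controls were at 0. Frmd5 (-4.27), Cxcr4, a chemokine receptor (-2.83), Hist1h2ap (-2.76), Pgf (-2.37) and Lrat, which esterifies retinol (-2.34), fell. Ccl19 (-0.98), Ccl21a (0.59), Il7 (0.17), Grem1 (0.58), Bst1 (-0.09), Cxcl13 (0.46) and Madcam1 (-0.75) did not pass. Of 10253 genes 59 rose and 83 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, on 38 cells in control 1, 107 in Notch2 cKO 1, 310 in control 2 and 301 in Notch2 cKO 2. EdgeR called 0 without the batch term (54 up and 45 down unadjusted) and 0 without control 1, Notch2 cKO 1 or control 2 (from 61 to 152 up and from 39 to 111 down unadjusted). It called 53 without Notch2 cKO 2, and DESeq2 with the batch term called 1.

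In adventitial-like cells (clusters 6 and 14) H2-Aa rose from 13.6 ± 9.85 to 48.7 ± 31.6 CPM (SD, n = 2; log2 1.91, SE 0.34), and so did Igkc, an immunoglobulin gene of B cells (2.02), Adamts17 (2.93), Plxna4 (1.82) and Esrrg (1.74). Cd79a stood at 0 and 12.7 CPM in cluster 14 of control 1 and Notch2 cKO 1 and at 0.885 and 4.59 in control 2 and Notch2 cKO 2, Ms4a1, another B cell gene, at 0 and 10.2 in batch 1 and 0 and 0 in batch 2, and H2-Aa at 0 and 14.0, and 2.66 and 3.06. In cluster 6 H2-Aa stood at 27.8 and 104, and 9.06 and 32.7 CPM, and Cd79a at 0 and 0.915, and 3.80 and 2.09. Vtn fell from 128 ± 36.3 to 35.2 ± 3.94 CPM (log2 -1.80, SE 0.30), as did Ptn (-1.78), Il31ra (-2.09) and Frmpd4 (-2.20). Ccl19 (-0.76), Ccl21a (-0.37), Il7 (0.06), Grem1 (0.97), Bst1 (0.71), Cxcl13 (0.46), Cd34 (-0.28) and Pi16 (-0.14) did not pass. In control 2 and Notch2 cKO 2 Ccl21a stood at 392 and 358 CPM in cluster 6 and at 582 and 398 in Schwann cells. Ccl19 stood at 361 and 315 CPM in cluster 6 and at 199 and 78.8 in Schwann cells. RNA carried over from other cells was not tested for these 2 chemokines. Of 12019 genes 34 rose and 17 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 0 by DESeq2 (49 up and 83 down at an unadjusted p under 0.05). Without the batch term edgeR called 0 (33 up and 31 down unadjusted), without control 1, Notch2 cKO 1, control 2 or Notch2 cKO 2 also 0 (from 34 to 123 up and from 21 to 266 down unadjusted). Without TMM factors 81.8% of 11 calls were up against 66.7%, and other random seeds of the clustering gave 1, 38 and 15 genes. Cluster 6, with 2253 of the cells against 719 in cluster 14, was led by Mgp, Fbln1 and Fmo2, had no adventitial marker among its 10 leading genes and held 34.8, 76.8, 31.0 and 28.3 CPM of Pi16 in control 1, Notch2 cKO 1, control 2 and Notch2 cKO 2, against 2693, 3732, 1608 and 1959 in cluster 14. At resolution 0.5 a cluster of 2958 cells led by several of the same genes was named Inmt-positive medullary and 577 cells were named adventitial.

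Whether the genotype effect differed between T-zone reticular-like and adventitial-like cells was tested directly. It was more positive in T-zone reticular-like cells for 86 genes and more negative for 64 of 14304, by edgeR's quasi-likelihood test of the subset by genotype term with libraries as a block and Benjamini-Hochberg adjustment. Cxcl14 had log2 fold changes of 6.99 in T-zone reticular-like and 0.01 in adventitial-like cells (difference 7.19, SE 0.45), and Cilp of 4.27 and 0.26 (4.13, SE 0.55). The adventitial-like values pool 2 clusters that differed. In cluster 6 both genes were higher in Notch2 cKO, at 2.32 and 25.6 CPM (batch 1) and 3.21 and 17.6 (batch 2) for Cxcl14 and at 55.6 and 181, and 49.1 and 153, for Cilp. In cluster 14 they stood at 11.9 and 6.36, and 51.4 and 10.7, for Cxcl14 and at 23.9 and 59.8, and 435 and 33.7, for Cilp. The T-zone value of Cxcl14 pools unlike clusters too. It stood at 2.16 and 4.08 CPM (batch 1) and 0.153 and 2.52 (batch 2) in cluster 1, and at 0 and 5.84, and 0.147 and 1.17, in cluster 3. In cluster 11 it stood at 0 and 20.7, and 6.38 and 79.5, and in cluster 0, which held few control cells, at 0 and 117, and 30.6 and 90.8. The difference between T-zone reticular-like and adventitial-like cells was not tested for each cluster. Hes1 had values of -2.22 and -0.22 (difference -2.02, SE 0.33), Notch3 of -2.74 and -0.61 (-2.10, SE 0.42, with -1.74 and 0.12 in the batches for the adventitial-like value) and Glycam1 of -2.96 and 2.40 (-5.20, SE 0.50). The T-zone value of Glycam1 turned positive with the looser (1.10) and stricter (0.70) cell filters, random seed 2 (0.82) and clusters 1 and 11 alone (1.70), where the difference was not tested. Its adventitial-like value did not pass by itself (adjusted p = 0.133 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and came from batch 2 (5.14 and 4.55 CPM in control 1 and Notch2 cKO 1, 1.07 and 10.5 in control 2 and Notch2 cKO 2; log2 -0.13 and 2.74). In batch 2 Glycam1 was also higher in Notch2 cKO among perivascular-like (15.2 and 27.7 CPM) and B cells (11.1 and 21.6), and RNA from other cells was not tested for it. Without the library block 31 genes passed, 25 positive and 6 negative.

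**Figure D3:**
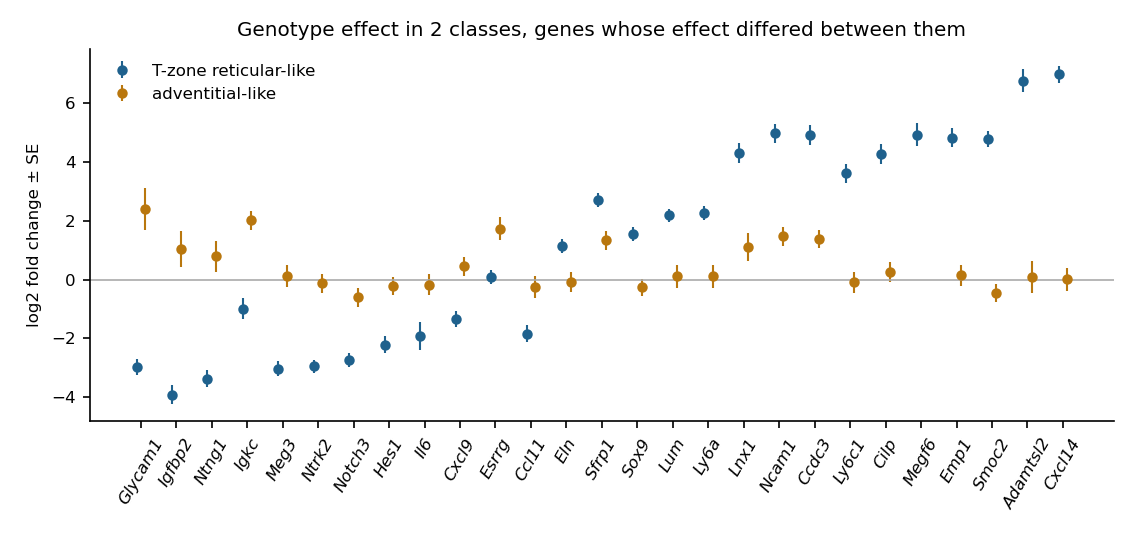
Log2 fold change (y axis, points, with SE as lines) of Notch2 cKO against control in T-zone reticular-like and adventitial-like cells for 27 named genes whose effect differed between the classes (Megf6 had too few counts for a value of its own in adventitial-like cells). Glycam1 stood at -2.96 (1.70 in clusters 1 and 11 alone) and 2.40 (-0.13 in batch 1), and Cxcl14 at 6.99 and 0.01 (higher in Notch2 cKO in cluster 6 of the adventitial-like cells in both batches, lower in cluster 14).

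Perivascular-like cells, the mural cells of vessels, came mostly from batch 2 (42, 66, 2089 and 1338 cells in control 1, Notch2 cKO 1, control 2 and Notch2 cKO 2). Bloc1s1, a gene of lysosome-related organelle assembly, fell from 101 ± 27.4 to 40.1 ± 23.0 CPM (SD, n = 2; log2 -2.07, SE 0.40), and Smim26 (-2.43), Rpa3 (-2.0) and Il31ra (-1.88) fell too. Notch3 (-0.24), Hes1 (-0.01) and Heyl (-0.03), named here after their values were seen, did not pass, and neither did Ccl19 (-1.08), Ccl21a (-1.02), Il7 (-0.43), Grem1 (-0.01), Bst1 (-0.68), Cxcl13 (-0.45) or Cd34 (-0.20). RNA carried over from other cells was not tested for Ccl19 and Ccl21a here. Of 11762 genes 2 rose and 13 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fit without the batch term called 3 genes up and 1 down, with 0 shared.

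The shares of fibroblast-like cells per class were compared last, in clusters built without the genes called between genotypes. T-zone reticular-like cells made up 43.3% (95% exact Clopper-Pearson interval 42.2 to 44.4) of control 1, 43.4% (42.2 to 44.5) of Notch2 cKO 1, 33.4% (32.5 to 34.2) of control 2 and 41.6% (40.7 to 42.6) of Notch2 cKO 2, and the intervals cover counting error only. Group means differed by 4.17 points (0.0752 in batch 1 and 8.27 in batch 2, and -0.796 without control 2). Adventitial-like cells differed by 4.68 points (6.53 and 2.82, but 0.970 at resolution 0.5 and 0.854 without doublet removal), Cxcl9- or interferon-high by 1.37 (1.0 and 1.74), follicular dendritic-like by 0.800 (1.04 and 0.559, with -0.245 without control 1, -0.00364 without Notch2 cKO 2 and 4.09 with clustering on all variable genes) and marginal reticular-like by 0.802 (-1.23 and 2.83, with -0.710 without Notch2 cKO 2). None passed an exact two-sided permutation test, in which 2 libraries against 2 cannot give a p under 0.333 (adjusted p 0.833, and 1.0 for the marginal class). Unnamed clusters held 44.8%, 37.4%, 51.7% and 35.5% of control 1, Notch2 cKO 1, control 2 and Notch2 cKO 2. By an edgeR quasi-likelihood test of cell numbers with batch as a term, cluster 0 (led by Sncg and Ly6h among the genes clustered on) was higher in Notch2 cKO (log2 7.72, Benjamini-Hochberg adjusted p = 6.47e-07), as was cluster 8 (Ptprt, 3.03). Clusters 3 (Slc7a11, Ccl19, -2.84) and 5 (Srxn1, Ptgs2, Il6, -2.08) were lower by the same test. The clusters were drawn from the same expression data in which the genotypes differed, and only genes past the test were left out. This test thus cannot tell a gain or loss of cells from cells whose expression changed and that fell into another cluster. The T-zone difference was -14.6 points with a stricter cell filter, -20.4 with clustering on all variable genes and 28.3 with another random seed, so its direction was not settled here.

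**Figure D4:**
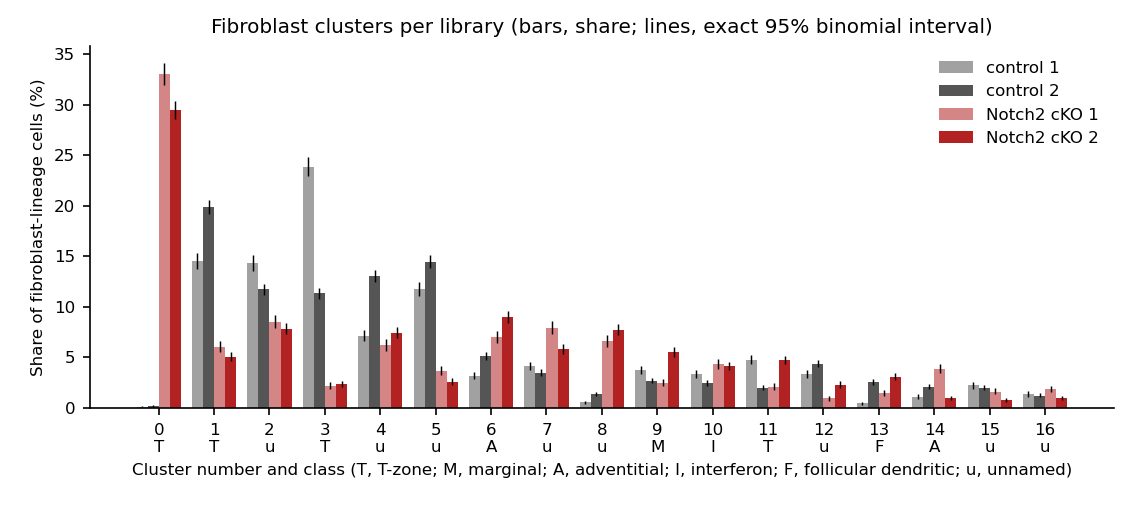
Share of fibroblast-like cells (y axis, %) in each cluster (x axis) and library, with exact 95% binomial intervals as lines. Cluster 0 held 33.0% and 29.5% of the Notch2 cKO libraries and 0.121% and 0.173% of the controls.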

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

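The tests of cluster shares as the whole cause of lower Notch3, Heyl and Hes1, of non-littermate controls, of summed endothelial markers, of less endothelial RNA, of endothelial markers other than Plvap and of the share of the inflammatory cluster were chosen only after the result was seen. The other tests were written before their first result and were computed again, with the same bounds, after the doublets removed had changed slightly.

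The genotype effect differed between T-zone reticular-like and adventitial-like cells for 27 of the 93 named genes tested, by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment (adjusted p from 9.00e-05 for Cxcl14 to 0.0469 for Notch3). A more negative effect in T-zone reticular-like cells, as log2 differences, was seen for Glycam1 (-5.20), Igfbp2 (-4.28), Ntng1 (-4.02), Igkc (-3.22), Meg3 (-3.07), Ntrk2 (-2.84), Notch3 (-2.10), Hes1 (-2.02), Il6 (-1.84), Cxcl9 (-1.77), Esrrg (-1.67) and Ccl11 (-1.61). A more positive effect was seen for Eln (1.24), Sfrp1 (1.40), Sox9 (1.80), Lum (2.09), Ly6a (2.16), Lnx1 (3.19), Ncam1 (3.4), Ccdc3 (3.55), Ly6c1 (3.77), Cilp (4.13), Megf6 (4.31), Emp1 (4.90), Smoc2 (5.39), Adamtsl2 (6.84) and Cxcl14 (7.19). The T-zone direction of Glycam1 turned with the looser filter (1.10), the stricter one (0.70), random seed 2 (0.82) and the 2 clusters that pass the check (1.70), and the difference between classes was not tested there. Its adventitial-like value (2.40) came from batch 2 (-0.13 and 2.74 in the batches), where Glycam1 was also higher in Notch2 cKO among perivascular-like (15.2 and 27.7 CPM) and B cells (11.1 and 21.6), and RNA from other cells was not tested for it. The adventitial-like values of Cxcl14 (0.01) and Cilp (0.26) pool cluster 6, where both were higher in Notch2 cKO in both batches (Cxcl14 2.32 and 25.6 CPM, and 3.21 and 17.6, Cilp 55.6 and 181, and 49.1 and 153), and cluster 14, where control 2 stood highest (51.4 CPM for Cxcl14 and 435 for Cilp), so the pooled values do not describe cluster 6, and the differences were not tested for each cluster. Many of these genes were named for large effects in T-zone reticular-like cells, so the number that differ is not an unbiased count.

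Notch3, Heyl and Hes1, a Notch receptor and 2 transcriptional repressors of the pathway, were lower in Notch2 cKO fibroblast-like cells. Less RNA from perivascular cells is argued against as the whole cause, since 10 other perivascular markers had a median log2 fold change of -0.43 (SD 0.56) against -2.24 for Notch3. Myh11, 1 of these markers, did fall in both batches (77.3 and 13.3 CPM in control 1 and Notch2 cKO 1, 112.5 and 49.0 in control 2 and Notch2 cKO 2), so a part from such RNA is not excluded. Other shares of the clusters are argued against as the whole cause. Notch3 and Hes1 averaged -1.32 within marginal reticular-like cells (-1.74 and -1.05 in the batches). The 3 genes averaged -1.12 with every cluster at the same share, and -0.96 without 3 clusters of under 50 cells in a library. The SD of 0.0530 was taken across the genes and does not measure the spread between libraries. By gene the equal-share values in the batches were -1.31 and -0.99 for Notch3, -1.27 and -1.0 for Heyl and -0.63 and -1.48 for Hes1. Without the 3 clusters Hes1 stood at -0.53 and -1.29. The mean of the 3 genes was -2.09 before shares were made equal. How much of that fall came from shares is not settled, since cells whose expression changed could fall into another cluster. Cluster 0, for one, held 0.121% and 0.173% of the controls and 33.0% and 29.5% of Notch2 cKO. In cluster 3 Notch3 was not lower (226 and 290 CPM in control 1 and Notch2 cKO 1, 227 and 260 in control 2 and Notch2 cKO 2) and Hes1 was higher in batch 1 (222 and 418). Heyl stood there at 22.3 and 23.35 CPM in batch 1 and 20.0 and 14.8 in batch 2. Non-littermate controls in batch 1 are argued against by batch 2, which compared littermates, with a mean of -1.89 (from -2.12 to -1.73). For the part within clusters, lower Notch signalling after targeting of Notch2 may account for the pattern, as a hypothesis found on the same data and not itself tested here, for which the deletion and the cleaved Notch2 protein would have to be measured.

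Glycam1, Madcam1, Stc2 and Il13ra2, which lead cluster 3 once called genes are counted, were lower in Notch2 cKO fibroblast-like cells, by a mean log2 fold change of -1.94. RNA from blood endothelial cells, which the CD31-negative sort would remove, could account for it by the summed level of 7 endothelial markers, which in cluster 3 was 2.85 (control 1) and 2.35 (control 2) times that of other fibroblast-like cells, but Plvap carried this (211 and 220 CPM against 69.2 and 72.8). The other 6 markers stood at 0.506 and 0.383 times (upper bounds 0.821 and 0.455), which argues against whole endothelial cells, and 5 markers had a median of 0.0202 (SD 1.16) in all fibroblast-like cells, which argues against less endothelial RNA in Notch2 cKO. By the test at equal shares, fewer cells of cluster 3 cannot be told apart from lower levels within cells for the 4 genes as a set. With every cluster at the same share the mean was -0.71 (SD across the genes 0.27, -0.60 and -0.82 in the batches) and the spread left it open. This mean includes cluster 0, with 10 cells in control 1, where Madcam1 stood at 33.0 CPM, and 21 in control 2. It was not computed without clusters of few cells. Inside cluster 3 Glycam1 (75.2 and 9.73 CPM in control 1 and Notch2 cKO 1, 104 and 23.8 in control 2 and Notch2 cKO 2) and Stc2 (248 and 191, 201 and 110) were lower in both batches, so fewer cells leave the lower Glycam1 and Stc2 there unaccounted for, whereas Madcam1 (91.7 and 119, 124 and 50.2) and Il13ra2 (105 and 125, 188 and 160) were higher in batch 1. In cluster 10 all 4 were lower in both batches, namely Glycam1 (32.1 and 1.67, 80.6 and 7.73), Madcam1 (46.8 and 19.2, 50.6 and 11.5), Stc2 (130 and 33.4, 67.5 and 24.4) and Il13ra2 (92.3 and 11.7, 81.3 and 14.9). Fewer cells of cluster 3 leave this fall unaccounted for. In cluster 1, however, Madcam1 (2.87 and 4.90) and Il13ra2 (16.5 and 31.0) were higher in batch 1. At low levels Glycam1 was higher in both batches in clusters such as 11 (3.01 and 13.8, 1.59 and 13.5) and 4 (1.77 and 3.97, 6.01 and 37.5). Glycam1 UMIs were found in 3.24% and 0.927% of fibroblast-like cells in batch 1, but in 3.81% and 6.22% in batch 2. Its lower summed level thus does not describe every cluster.

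Il6, Lif, Cxcl5 and Ptgs2, inflammatory genes that lead cluster 5, had a mean log2 fold change of -1.73, and of the 4 Lif and Cxcl5 passed the test in all fibroblast-like cells. A weaker response to dissociation common to both batches is argued against by the 12 immediate early genes, with a median of 0.0647 (SD 0.344, 0.34 and -0.31 in the batches). For batch 2 alone, where that median was negative, these genes do not settle it. Less RNA from macrophages or monocytes is argued against by 6 markers, with a median of 0.63 (SD 0.948). Fewer cells of cluster 5 cannot be told apart from lower levels within cells for the 4 genes as a set, since with every cluster at the same share the mean was -0.65 (SD across the genes 0.57), at -0.0296 in batch 1 and -1.27 in batch 2. By gene these values were 0.01 and 0.11 for Cxcl5, which was not lower at equal shares in either batch, 0.19 and -1.99 for Il6, 0.21 and -1.17 for Ptgs2, and -0.53 and -2.01 for Lif. They include cluster 0, with 10 and 21 control cells. Inside cluster 5 Il6 (668 and 659 CPM, and 1051 and 275), Lif (139 and 140, and 256.5 and 75.4) and Ptgs2 (1790 and 1731, and 2250 and 1136) were clearly lower in batch 2 only. Cxcl5 stood there at 337 and 448, and 174 and 157 CPM. Fewer cells of cluster 5 leave the lower Il6, Lif and Ptgs2 inside it in batch 2 unaccounted for. Cells whose expression changed could also fall into another cluster, so equal shares do not separate shares from levels within cells. Differences between animals or in the handling of single libraries were not tested.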

How the results depend on the processing

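Named classes alone, leaving out the inflammatory cluster (5) or the T-zone reticular-like clusters, clustering without Harmony, with Harmony over libraries or with other random seeds, the 2 T-zone clusters that pass the check on all genes, and leaving out libraries for the shares were chosen only after the data were seen.

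Genes called by edgeR depended most on the batch term, that is the replicate block. Without this block 0 genes were called in all fibroblast-like, T-zone reticular-like, Cxcl9- or interferon-high, marginal reticular-like, follicular dendritic-like and adventitial-like cells (at an unadjusted p under 0.05 up and down 244 and 193, 404 and 361, 270 and 290, 55 and 50, 54 and 45, and 33 and 31), 4 in perivascular-like cells, and 31 for the difference between classes without the library block. In simulated data with batches as in these libraries, where the batch model held by design, the fit without the block recovered 0% of genes changed 8 times in all fibroblast-like and T-zone reticular-like cells, and the cause was not tested further. Notch2 without the block was -0.98 and -1.02 in T-zone and interferon-high cells and missed the test. With 1 library left out, and no batch term, counts lay between 0 and 6 in all fibroblast-like, 0 and 0 in T-zone reticular-like, 0 and 0 in interferon-high, 0 and 1 in marginal, 0 and 53 in follicular dendritic-like and 0 and 0 in adventitial-like cells, with the unadjusted counts given above and DESeq2 counts, with all libraries, of 449, 605, 146, 18, 1 and 0 (49 up and 83 down unadjusted in the last).

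The cause was not tested for the following counts, except that no low-count filter tests more genes. In all fibroblast-like cells (341) no TMM gave 96, no low-count filter 869, the looser cell filter 196, the stricter one 210, named classes alone 224 and the T-zone clusters left out 11. In T-zone reticular-like cells (1042) the stricter filter gave 66, no Harmony 83, random seed 2 gave 678 and the 2 clusters that pass the check 264. In interferon-high cells (673) no TMM gave 353, DESeq2 146, the looser filter 421, the stricter one 379, no doublet removal 244 and no Harmony 287. In marginal cells (132) the looser filter gave 54, no doublet removal 77, no Harmony 429 and random seeds 1, 2 and 3 gave 29, 37 and 31. In follicular dendritic-like cells (142) random seed 1 gave 35. In adventitial-like cells (51) no TMM gave 11, the looser filter 8, the stricter one 6, no doublet removal 14 and random seeds 1 and 3 gave 1 and 15. Of 7 gene lists past the threshold in each comparison 0 held by camera with an estimated correlation, and fry called 1 in all fibroblast-like (Notch targets) and 0 in T-zone reticular-like cells. Camera with an estimated correlation also missed the changed list in simulated data.

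Share differences reversed under several clusterings, and the cause was not tested. For T-zone reticular-like cells (4.17 points) they were -20.4 on all variable genes, -14.5 at resolution 2, -14.6 with the stricter cell filter, -2.82 without Harmony and from -0.796 to 9.14 with 1 library left out. For interferon-high cells (1.37) they were -0.628 on all variable genes, -0.935 at resolution 0.5, -0.0501 without doublet removal and -0.489 with random seed 3. For marginal cells (0.802) they were -0.814 on all variable genes, -8.56 at resolution 2, -8.11 with each batch alone, -2.86 with the looser filter, -7.05 without Harmony, -7.46 with Harmony over libraries, -1.81 and -0.442 with random seeds 2 and 3 and from -0.710 to 2.31 with 1 library left out. For follicular dendritic-like cells (0.800) they were 4.09 on all variable genes (3.96 and 4.23 in the batches), 2.33 without Harmony, 0.0772 with Harmony over libraries and from -0.245 to 1.85 with 1 library left out. For adventitial-like cells (4.68) the mean difference kept its sign but was 0.970 at resolution 0.5, 0.854 without doublet removal and 1.48 with Harmony over libraries, and in batch 2 it was -0.605 and -1.2 in the first 2 of these.

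Among genes and lists, 100 stayed on the same side of the test with the same direction with DESeq2, 107 without doublet removal, 89 with the looser filter and 83 without TMM, where 24 were weaker. With the stricter filter 49 were the same, 35 weaker and 13 reversed, and with 1 library left out 93 or 94 were weaker under each choice. In all fibroblast-like cells reversals were Ccl21a (-0.18 in named classes, -0.19 to 0.38 with 1 library left out), Il7 (-0.0510 in named classes, -0.18 to 0.26), Bst1 (-0.17 in named classes, -0.17 to 0.34), Cxcl13 (-1.17 to 1.58), Pi16 (-1.13 to 1.96) and Cd34 (0.25 without the replicate block, 0.0157 without TMM, 0.00365 with the stricter filter, 0.0799 in named classes, 0.0812 without T-zone clusters, -0.95 to 0.87), none of which passed the test. The NF-kB list (fry, adjusted p = 0.991) and the immediate early list (without the replicate block, adjusted p = 0.990) turned sign without passing. In T-zone reticular-like cells the stricter filter reversed Notch1 (0.0621), Glycam1 (0.70), Ccl21a (0.27), Il7 (0.0472), Grem1 (-0.0527), Bst1 (0.0278), Cxcl13 (-1.5), Ackr3 (-0.87), Eln (-0.14), Cxcl2 (0.17), Sfrp2 (-1.3) and Myl9 (0.56). The looser filter reversed Glycam1 (1.10), Bst1 (0.26), Cxcl9 (0.93) and Col14a1 (0.78), and random seed 2 the same 4 (0.82, 0.17, 0.51 and 0.51). The 2 clusters that pass the check reversed Glycam1 (1.70), Ccl21a (0.28), Bst1 (0.15), Cxcl13 (-0.22), Cxcl9 (0.38), Sfrp2 (-0.41) and Myl9 (0.43), no TMM Il7 (0.0217), and 1 library left out Il7 (-0.28 to 0.18), Pi16 (-0.35 to 1.59), Cxcl13 (-0.0670 to 2.34) and Tnfsf11 (-3.41 to 0.18). The cause was not tested. Median depth of 2086 and 2913 UMIs in batch 1 against 6401 and 7933 in batch 2 limits what batch 1 adds for genes with few counts.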

Other observations

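Some genes and clusters in no comparison of the report also differed. In unnamed fibroblast-like clusters edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 112 genes up and 104 down in cluster 2, 94 and 55 in cluster 4, 95 and 79 in cluster 5, 105 and 92 in cluster 7, 59 and 78 in cluster 8, 45 and 47 in cluster 12 and 7 and 3 in cluster 15. Cluster 16 had 0 calls (105 up and 186 down at an unadjusted p under 0.05, with no other tool run there). Notch2 was lower in cluster 5 (log2 -1.12, adjusted p = 0.0324) and cluster 8 (-1.35, adjusted p = 0.0140) by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

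Markers of other cell types were also counted in all fibroblast-like cells. Among 11 perivascular markers 2 fell (Notch3 and Myh11), among 5 measured T cell markers 1 fell (Trac) and among 5 measured dendritic cell markers 1 rose (H2-Aa), by edgeR's test. Of 5 Schwann cell markers 1 rose (Mbp), and of 5 markers of Inmt-positive medullary cells 1 rose (Cxcl14). Epithelial clusters made up 0.703% of control 1, 0.205% of Notch2 cKO 1, 0.354% of control 2 and 0.253% of Notch2 cKO 2.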
